A study of Mus musculus with 81 samples.

How the data were processed

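The series holds 81 arrays, each hybridised with total RNA from the whole blood of 1 female C57BL/6 mouse aged 6 to 8 weeks. Per the labels' protocols, the animals received a single whole-body X-ray dose from the SARRP, an X-ray irradiator for small animals, at 1.05 Gy/min, and the 0 Gy animals were sham irradiated. The sample labels give 27 groups of 3 animals. Batch A holds 0, 2, 4 and 8 Gy and batch B holds 0, 12 and 15 Gy, each at 6 h, 24 h, 48 h and 7 d, with no 15 Gy group at 7 d. The treatment protocol names doses up to 12 Gy, while the sample titles reach 15 Gy. The series description also lists 1 Gy, and that dose is not analysed here. The tissue field reads whole body and the source field whole blood, and the source field was followed.

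Per the labels, RNA was isolated with a Ribopure kit, dephosphorylated, denatured and end-labelled with Cy-3. Per the file headers, the deposited scanner files are 1-colour Agilent arrays read with Agilent Feature Extraction 11.5.1.1, whose processed signal is an intensity after background subtraction, with no scaling between arrays. The deposited series matrix also holds intensity values. Set against the scanner files, most of its columns follow the summed intensity per probe times 1 factor per array, from 0.281 to 14.1, with a median of 71.6% of probes within 1% of that factor. On 4 arrays fewer than 60% did, and the columns of the 6 h 15 Gy replicate 1 (0%) and the 6 h batch A sham replicate 2 (2.27%) do not follow such a factor. Its lowest value is 0.01, and neither labels nor headers state how the factor was chosen. All 81 columns were matched, and the matrix served as an alternative source. The headers name the mouse build mm9, and no coordinates were used. The files pair each probe with a mouse miRNA name, which is used here without its species prefix, and give no probe sequences, so base composition was not tested and members of a family that differ by few bases, such as let-7, may share signal.

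Each array carries 52044 spots, of which 2164 are controls, and 3105 probes for 1247 mouse miRNAs. Spots that Feature Extraction marked as outliers (0.932 to 10.7% per array) were left out, the processed signal was averaged over the other spots of a probe, and a probe was taken as detected where at least 50% of its spots were well above background. Signals were divided by the array's 75th percentile over the 121 probes (72 miRNAs) detected on all 81 arrays, floored at 0.00373 (the median over arrays of the 5th percentile of scaled detected signal) and taken to log2. A miRNA was tested on the mean log2 value of its probes that were detected on all 3 arrays of at least 1 group. This kept 414 probes and 237 miRNAs, 67 of them with 1 probe. No spot was saturated. Values at the floor have no order or spread, so the pooled standard error of a miRNA that is below background in most groups can be smaller than its spread where it is measured. Where all 3 arrays of a group were below background or at the floor, the fold is given as a lower bound, against the floor or the lowest signal well above background on each of those arrays, whichever was higher. Where that limit lay beyond the other group's level, no fold is given. Where only some arrays of a group lay at the floor, they enter at that value. The printed change is then a least size if that group is the lower, and may be too large if it is the higher.

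Tests were run in R 4.3.3 with limma 3.58.1, and files were read with the data.table package, version 1.17.8. limma fitted 1 mean for each of the 27 groups over all 81 arrays, with empirical Bayes variances. Every adjusted p below is limma's moderated test, or limma's camera for lists, with Benjamini-Hochberg adjustment, two-sided, called at an adjusted p under 0.05. A permutation test of 3 arrays against 3 cannot give a p below 0.1, so none was used. Errors on log2 changes are standard errors (SE) from that fit with n = 3 per group unless SD is written. The 19 dose groups were each set against the sham group of their batch and time. Further tests were a linear dose trend over 0 to 8 Gy, sham B against sham A, 15 against 12 Gy, and an F test of whether the 8 Gy or 12 Gy change differed among times. The 8 and 12 Gy changes, which share no array, were compared by a correlation across miRNAs with a jackknife over the 12 arrays. On data simulated for 8 Gy against sham at 6 h (237 miRNAs, 60 of them changed, 20 simulations), the fit recovered 55.2% of changes of 0.5, 90.0% of changes of 1 and 98.2% of changes of 2 on the log2 scale, and 3.4% of calls were false. The simulated noise was independent among miRNAs, had the same spread in all groups and was not floored. The real arrays differ in each of these, so the shares do not carry over to them.

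Named miRNAs followed a rule written before the data were examined, as were the lists, the tests and all alternatives not marked otherwise. For 8 and 12 Gy at each time it takes the 6 largest rises and 6 largest falls among called miRNAs whose irradiated arrays all lay on 1 side of all sham arrays. For other comparisons it takes 3 and 3 (trends: p alone), and for the tests by time the 6 smallest p. Separation of 3 arrays from 3 arises by chance in 10% of comparisons. In every comparison it adds miR-150-5p, miR-342-3p, miR-142-3p, miR-223-3p, miR-451a, miR-16-5p, miR-144-3p, miR-126-3p, miR-130a-3p, miR-34a-5p, miR-21a-5p and the let-7 family, and up to 4 examples per list. The 11 lists are erythroid, lymphoid, myeloid, pan-leukocyte, platelet, p53-linked, the miR-17-92 and paralogue clusters, the let-7 family, the miR-29 and miR-30 families, inflammatory, and other tissues. Lists with at least 3 tested members were tested with camera (preset correlation 0.01, and an estimated correlation beside it), adjusted over 209 tests.

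Alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes, the series matrix, the total signal per miRNA, only the compared groups, the replicate number as a block, the slide as a block (a random block where no fixed block could be estimated), and each array left out in turn. The mean pixel signal named for normexp is not in the files, so the median was used. Scaling over all probes could not be run, because that percentile was 0 or lower on 6 arrays. Chosen after the data were seen were a lower floor (0.00295), the slide as a random block in comparisons where the slide also crosses the groups, only slides that hold both groups, and a fit without the 1 array of high negative-control spread. The 81 arrays lay on 11 slides scanned on 4 days. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The number of arrays, 3 per group, limits the precision of every value.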

Results

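The microRNA (miRNA) content of mouse whole blood was measured on 81 arrays, 3 animals in each of 27 groups. Animals received whole-body X-ray doses of 2, 4 or 8 Gy (batch A) or 12 or 15 Gy (batch B), and each batch had its own sham-irradiated animals. Blood was taken at 6 h, 24 h, 48 h and 7 d, with no 15 Gy group at 7 d. Between 163 and 485 of the 3105 mouse probes lay above background on an array, 5.25 to 15.6%, and 237 miRNAs were tested. The brightness of the arrays differed by group. Before scaling, the 75th percentile of the 121 probes detected on every array averaged 14884 ± 3663 (SD, n = 3) in the batch A shams at 7 d. It averaged 1585 ± 672 (SD, n = 3) after 8 Gy at that time. At 48 h it averaged 9377 ± 2039 (SD, n = 3) in the batch A shams and 24590 ± 1605 (SD, n = 3) after 8 Gy. Every change below is a log2 ratio after scaling to that percentile, so it is relative to this set of abundant blood miRNAs. The number of arrays, 3 per group, limits the precision.

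**Figure D1:**
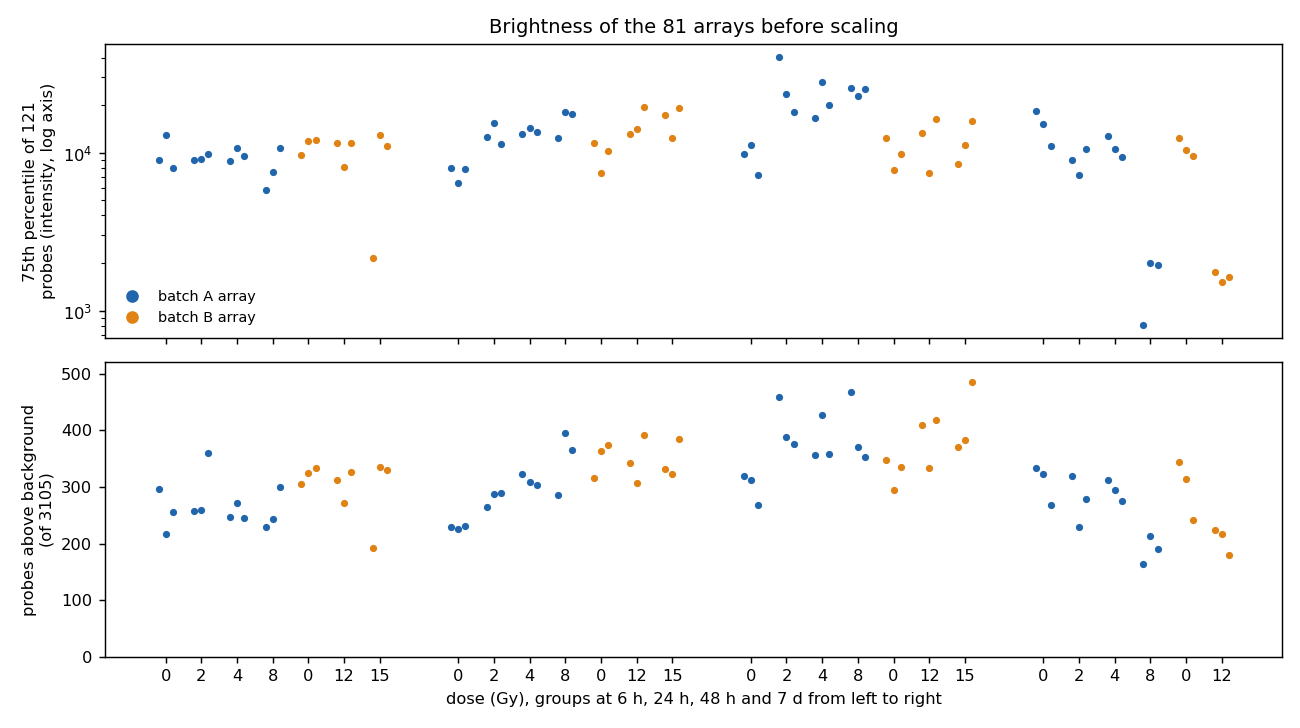
Brightness of each array before scaling, as the 75th percentile of the probes detected on all 81 arrays (upper panel, log axis), and its number of probes above background (lower panel), by dose and time. Each point is 1 array (blue, batch A; orange, batch B), and the 8 and 12 Gy groups at 7 d are the dimmest, with mean percentiles of 1585 and 1633.

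Which blood miRNAs respond within 6 h was asked for 5 doses. miR-223-3p, abundant in neutrophils and monocytes, rose by 1.30 ± 0.30 (SE, n = 3, adjusted p = 0.015) after 4 Gy and by 1.31 ± 0.30 (adjusted p = 0.0067) after 15 Gy. Its changes at 2, 8 and 12 Gy were 1.13, 1.02 and 0.92. miR-146a-5p, a feedback inhibitor of innate immune signalling, rose by 0.88 ± 0.19 after 8 Gy (adjusted p = 0.0063) and was at least 1.71-fold higher than shams at the floor after 12 Gy (adjusted p = 0.039). After 15 Gy, miR-342-3p, abundant in lymphocytes, also rose, by 1.23 ± 0.26 (adjusted p = 0.0044), as did miR-328-3p by 0.96 ± 0.30. The myeloid list (miR-223-3p and the miR-23a, miR-24 and miR-27a miRNAs) was shifted up against the other miRNAs at 2 Gy (adjusted p = 0.025), 4 Gy (adjusted p = 0.0017) and 12 Gy (adjusted p = 1.8e-05). At these doses 0, 1 and 0 of its 4 members were called over all miRNAs and 3, 3 and 2 adjusted over the list alone. The 12 Gy shift holds with an estimated correlation (adjusted p = 0.036), while 2 Gy (adjusted p = 0.727 with an estimated correlation) and 4 Gy (adjusted p = 0.154 with an estimated correlation) do not.

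limma called 0 miRNAs at 2 Gy (42 at an unadjusted p under 0.05), 1 each at 4 Gy (28), 8 Gy (19) and 12 Gy (5), and 29 at 15 Gy (28 up and 1 down, or 16 up and 7 down with quantile normalization). At 15 Gy normexp correction called 9 and total gene signal 7, and with only the 6 compared arrays 0 were called at 4, 8, 12 and 15 Gy. The call of miR-223-3p at 4 Gy was lost without sham replicate 1 (1.21, adjusted p = 0.090), 4 Gy replicate 1 (1.25, adjusted p = 0.118) or replicate 3 (1.14, adjusted p = 0.292), though its change stayed near 1.30. The call of miR-146a-5p at 8 Gy was lost without sham replicate 1 (0.59, adjusted p = 0.199) or 8 Gy replicate 3 (0.72, adjusted p = 0.278). Its call at 12 Gy was lost in 5 of the 6 fits that left out an array, with adjusted p values of 0.086 to 0.523. At 15 Gy the count was 3, 5 and 4 without sham replicates 1, 2 and 3. It was 5 without 15 Gy replicate 1, where miR-328-3p changed by 0.31, and 48 without 15 Gy replicate 2. With the slide as a block the counts from 2 to 15 Gy were 9, 0, 0, 2 and 75, the last resting on the 1 dim 15 Gy array on the shams' slide.

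At 24 h the same 5 doses were compared with the shams to ask which miRNAs differ a day after exposure. miR-150-5p, a lymphocyte miRNA, fell to the floor on every irradiated array, so its size at each dose is open. It was at least 3.42-fold, 3.66-fold, 3.61-fold, 2.61-fold and 2.61-fold lower than in shams from 2 to 15 Gy. miR-142-3p, a miRNA of all blood cell lineages, changed by -2.05 ± 0.42, -1.85 ± 0.42, -1.47 ± 0.42, -2.45 ± 0.42 and -2.72 ± 0.42 (SE, n = 3) from 2 to 15 Gy, called at each. miR-140-5p fell by 2.36 ± 0.36 after 2 Gy and by 3.36 ± 0.36 after 15 Gy. miR-126-3p, known from endothelium and platelets, fell by 1.00 ± 0.22 after 8 Gy and 1.52 ± 0.22 after 12 Gy. miR-20a-5p and miR-20b-5p, of the miR-17-92 and paralogue clusters known for promoting proliferation, fell by 1.63 ± 0.25 and 1.5 ± 0.25 after 8 Gy. The mean level of miR-34a-5p was not above that of the shams at any dose. After 15 Gy its log2 levels were -7.67, -7.84 and -8.02, against -7.54, -7.08 and -7.25 on the sham arrays.

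The rises at 24 h included miR-466i-5p by 1.58 ± 0.34 (SE, n = 3) after 8 Gy and 1.81 ± 0.34 after 12 Gy, and miR-30c-5p by 1.36 ± 0.24 after 8 Gy. miR-423-5p rose by 1.89 ± 0.24 and miR-92a-3p by 1.64 ± 0.21 after 12 Gy, where miR-223-3p also rose, by 1.44 ± 0.30. let-7b-5p and let-7c-5p, members of a family that restrains growth genes, rose by 1.42 ± 0.24 and 1.21 ± 0.21 after 12 Gy. In all 6 of 9 family members rose and 2 fell, among them let-7f-5p, which fell by 0.56 ± 0.16. At 4 Gy 7 rose and 0 fell, though let-7e-5p (-0.39) reversed with normexp correction and let-7i-5p (-0.07) with quantile normalization. The largest falls after 12 Gy were miR-494-3p (-4.54 ± 0.61, with an SD of 2.89 among the shams), miR-6243 (-3.08 ± 0.49) and miR-3963 (-3.0 ± 0.51), and miR-5115 was at least 6.58-fold lower. Of the pan-leukocyte list 2 rose and 4 fell after 12 Gy. Of the lymphoid list 3 rose (miR-181a-5p, miR-181b-5p and miR-150-3p) and 2 fell (miR-150-5p and miR-342-3p). Neither list was called (adjusted p = 0.35 and 0.995).

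limma called 94 miRNAs (61 up, 33 down) after 2 Gy, 110 (84 up, 26 down) after 4 Gy, 70 (47 up, 23 down) after 8 Gy, 135 (79 up, 56 down) after 12 Gy and 124 (69 up, 55 down) after 15 Gy. The split depended on the scaling. In the same order of dose, normexp correction gave 21 up and 29 down, 33 and 21, 16 and 111, 42 and 46, and 38 and 48. Quantile normalization gave 58 and 39 at 4 Gy and 41 and 32 at 8 Gy. The series matrix gave 41 and 35 at 2 Gy, 52 and 30 at 4 Gy and 45 and 62 at 15 Gy. With only the 6 compared arrays, 25 were called at 8 Gy and 30 at 12 Gy. At 12 Gy that fit left the changes of miR-423-5p (1.89, adjusted p = 0.093), miR-92a-3p (1.64, adjusted p = 0.082) and miR-494-3p (-4.54, adjusted p = 0.109) as they were but did not call them. The 8 Gy change of miR-142-3p depended on single arrays. It was -1.16 without 8 Gy replicate 1 (adjusted p = 0.059) and -0.83 without replicate 2 (adjusted p = 0.146), neither called, and -2.41 without replicate 3.

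At 48 h changes were large after each of the 5 doses. miR-150-5p changed by -1.33 ± 0.18, -1.81 ± 0.18 and -2.29 ± 0.18 (SE, n = 3) after 2, 4 and 8 Gy, and it was at least 4.03-fold lower after 12 Gy. After 15 Gy it lay at or just above the floor (mean level -8.05), so its size there is open too. miR-223-3p rose by 1.62 ± 0.30, 2.37 ± 0.30, 2.78 ± 0.30, 2.50 ± 0.30 and 2.62 ± 0.30. miR-34a-5p, a direct target of p53, rose by 0.56 ± 0.19, 0.79 ± 0.19, 1.09 ± 0.19, 1.47 ± 0.19 and 1.57 ± 0.19. With normexp correction its changes at 2 and 4 Gy were -0.31 and -0.03 and its call at 8 Gy was lost (0.13, adjusted p = 0.709). The call at 2 Gy was also lost without 2 Gy replicate 1 (0.39, adjusted p = 0.111). miR-126-3p was at least 4.33-fold lower after 8 Gy and 4.29-fold lower after 12 Gy, at the floor in both.

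The largest rises at 48 h were miR-1187 (5.0 ± 0.46 after 8 Gy and 5.57 ± 0.46 after 12 Gy, SE, n = 3, from shams at or near the floor), miR-574-5p (4.93 ± 0.45 and 5.32 ± 0.45) and miR-466i-5p (4.16 ± 0.34 and 4.51 ± 0.34). Also among them were miR-193b-3p (3.93 ± 0.29 and 3.92 ± 0.29) and miR-328-3p (3.31 ± 0.30 and 3.96 ± 0.30). miR-423-5p was up by 3.49 ± 0.24 after 8 Gy and miR-3095-3p at least 15.1-fold higher after 12 Gy. The largest falls were miR-140-5p (-3.75 ± 0.36 and -2.93 ± 0.36), miR-3963 (-3.50 ± 0.51 and -3.07 ± 0.51) and miR-26b-5p (-3.16 ± 0.25 and -2.63 ± 0.25). miR-30e-5p fell by 2.99 ± 0.28 after 8 Gy and miR-374c-5p fell by 2.50 ± 0.30 after 12 Gy. In the let-7 family, let-7b-5p rose by 2.84 ± 0.24 and 2.89 ± 0.24 while let-7f-5p fell by 0.77 ± 0.16 and 0.58 ± 0.16. There 4 members rose and 2 fell after 8 Gy. After 12 Gy 6 rose and 1 fell, but let-7a-5p (-0.19) and let-7i-5p (-0.07) reversed with quantile normalization, and both and let-7e-5p in the series matrix.

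Of the 6 pan-leukocyte members, miR-140-3p rose and 5 fell after 2, 4 and 8 Gy (miR-142-3p by 2.36 ± 0.42 after 8 Gy, and miR-26b-5p as above), with the list not called (adjusted p = 0.124 at 8 Gy). The myeloid list had 3 members up (miR-223-3p, miR-23a-3p and miR-24-3p) and miR-27a-3p down after 8 and after 12 Gy (adjusted p = 0.842 and 0.949). The erythroid list had 2 up and 4 down after 8 Gy (adjusted p = 0.26) and the miR-17-92 and paralogue clusters 3 up and 7 down (adjusted p = 0.124). miR-451a, the dominant miRNA of red cells, fell by 1.19 ± 0.26 after 8 Gy, and its change was 0 with quantile normalization. That method gives the highest-ranked probes the same values on every array. As miR-451a had the highest mean level of all tested miRNAs (4.65), that 0 decides neither way. Among miRNAs of other tissues, miR-375-3p (pancreatic islets and gut), miR-200c-3p and miR-205-5p (epithelium) rose after 12 Gy. After 15 Gy 5 members rose and 0 fell, with miR-133a-3p and miR-133b-3p (muscle) added. The list was not called (adjusted p = 0.26 and 0.215). limma called 138 (91 up, 47 down), 150 (99, 51), 152 (101, 51), 159 (122, 37) and 169 (131, 38) miRNAs from 2 to 15 Gy. Quantile normalization gave 82 up and 65 down at 4 Gy, 89 and 72 at 8 Gy, and 79 and 70 at both 12 and 15 Gy. Normexp gave 38 and 75 at 2 Gy, 50 and 54 at 4 Gy and 56 and 60 at 8 Gy. The series matrix gave 56 and 54 at 2 Gy, 59 and 66 at 12 Gy and 57 and 70 at 15 Gy.

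**Figure D2:**
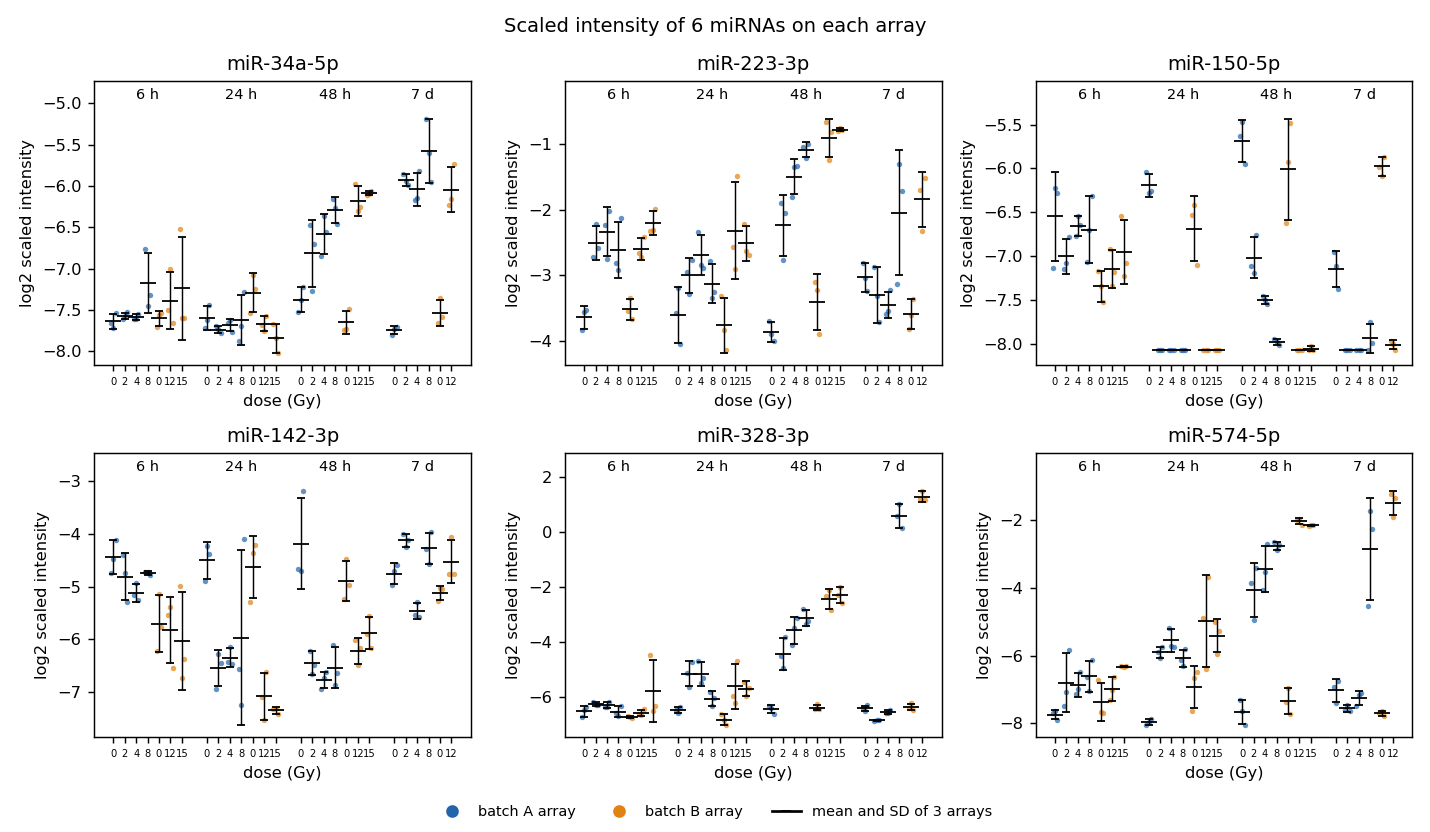
Scaled log2 intensity of 6 miRNAs on each of the 81 arrays, by dose and time (points, 1 array each, blue for batch A and orange for batch B; black, mean and SD of 3 arrays). miR-150-5p is lower after all 5 doses at 24 h and 48 h, and miR-328-3p is 6.99 and 7.65 higher after 8 and 12 Gy at 7 d.

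At 7 d, 4 doses were compared with the shams to ask which miRNAs differ a week after exposure. miR-34a-5p was up by 1.82 ± 0.19, 1.71 ± 0.19 and 2.17 ± 0.19 (SE, n = 3) after 2, 4 and 8 Gy. Its fitted change after 12 Gy was 1.49 ± 0.19. Its level lay below the lowest signal well above background on each dim 12 Gy array and on 8 Gy replicate 1. The size of its change after 8 Gy is therefore open, and after 12 Gy both its size and its direction are. Its 12 Gy call was lost in the series matrix (0.16, adjusted p = 0.581) and its 4 Gy call with normexp correction (1.08, adjusted p = 0.050). miR-150-5p lay at or just above the floor after 2 Gy (mean level -8.06), so the size of its fall is open, and was at least 1.85-fold lower after 4 Gy, though neither was called with normexp correction. After 8 and 12 Gy it lay below background on all 3 dim arrays, which gives no bound on its change, and with normexp correction it was 1.81 and 1.05 higher. After 8 and 12 Gy the red cell miRNA miR-144-3p rose by 2.36 ± 0.35 and 2.92 ± 0.35 and miR-451a by 1.34 ± 0.26 and 1.32 ± 0.26. With quantile normalization miR-451a was -0.60 and -0.74. The highest-ranked probes cannot rise under that method. As miR-451a had the highest mean level (4.65), these values do not decide its direction. miR-16-5p fell by 0.87 ± 0.17 and 1.85 ± 0.17. Of the 7 erythroid members tested, out of 11 in the list, 4 rose and 2 fell at each dose (adjusted p = 0.949 and 0.986). The platelet miRNA miR-130a-3p fell by 1.68 ± 0.15 and 2.27 ± 0.15, though with normexp correction it was 0.16 at 8 Gy and lost its call at 12 Gy (adjusted p = 0.658). miR-126-3p lay below background on all arrays after 8 and 12 Gy, which gives no bound on its change there.

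The largest rises at 7 d after 8 and 12 Gy were miR-328-3p (6.99 ± 0.30 and 7.65 ± 0.30, SE, n = 3), miR-296-5p (4.60 ± 0.22 and 5.38 ± 0.22) and miR-1187 (4.44 ± 0.46 and 6.06 ± 0.46). miR-3095-3p was at least 20-fold and 37.6-fold higher. miR-574-5p was up by 6.23 ± 0.45 after 12 Gy and miR-712-5p at least 18.9-fold higher after 8 Gy. The largest falls included miR-26b-5p (-2.92 ± 0.25 and -3.49 ± 0.25), miR-29a-3p (-2.71 ± 0.15 after 12 Gy) and miR-6366 (-3.85 ± 0.53 and -2.70 ± 0.53). miR-29c-3p was at least 3.94-fold and 3.95-fold lower. The miR-29 and miR-30 families, of which miR-29 restrains collagen genes, were shifted down after 8 Gy (adjusted p = 0.025, but adjusted p = 0.998 with an estimated correlation). There 6 of 8 members fell, also 6 adjusted over the list alone, and miR-30d-5p rose. After 12 Gy 2 rose and 4 fell (5 called adjusted over the list alone; adjusted p = 0.124). The p53-linked list was shifted up after 4 Gy (adjusted p = 0.0046, but adjusted p = 0.154 with an estimated correlation), with miR-34a-5p the only member called. In the let-7 family 2 rose and 4 fell after 8 Gy and 2 rose and 6 fell after 12 Gy, though with normexp correction let-7e-5p reversed to 2.17 after 8 Gy. After 12 Gy let-7b-5p rose by 2.36 ± 0.24 and let-7g-5p fell by 2.12 ± 0.11.

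limma called 46 miRNAs (23 up, 23 down) after 2 Gy, 4 (1 up, 3 down) after 4 Gy, 150 (91 up, 59 down) after 8 Gy and 161 (102 up, 59 down) after 12 Gy. On the dim 8 and 12 Gy arrays the lowest scaled signal well above background was 0.0149 to 0.0388, against a floor of 0.00373. Signal below background can therefore enter above the floor there, and some of the rises may come from it. How many do was not counted. Normexp correction gave 195 up and 18 down at 8 Gy and 196 and 19 at 12 Gy, moving the median of all miRNAs by 2.22 and 2.05, and 13 and 3 at 2 Gy, and it called 0 at 4 Gy. With only the 6 compared arrays 74 were called at 2 Gy and 27 at 4 Gy. Quantile normalization gave 79 and 84 at 12 Gy and 1 and 1 at 4 Gy. The series matrix gave 56 and 69 at 8 Gy, 59 and 93 at 12 Gy, and 1 and 0 at 4 Gy.

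**Figure D3:**
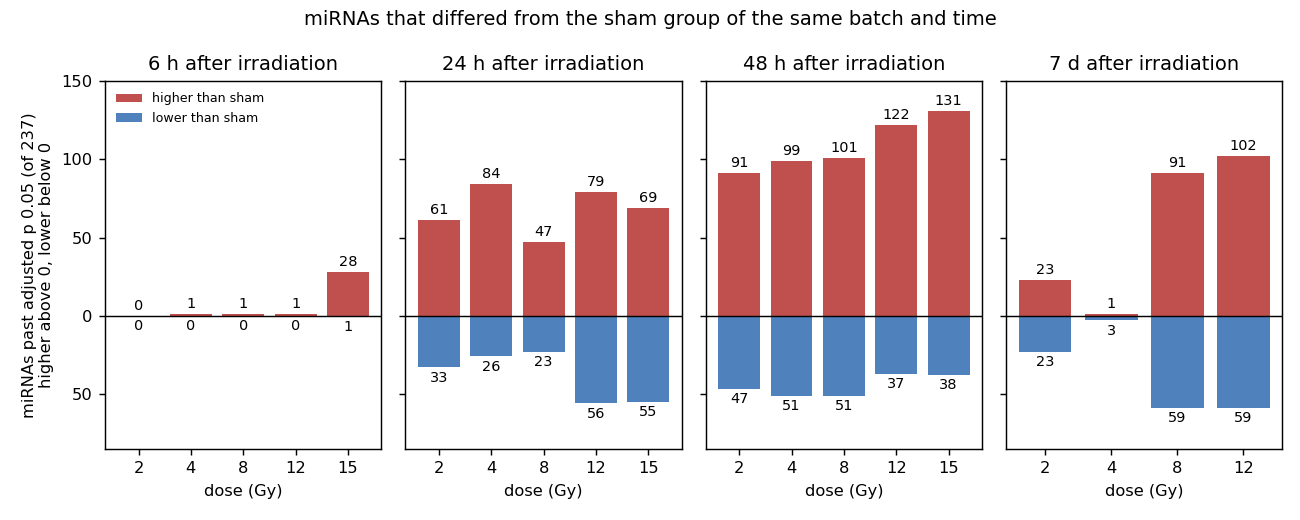
Number of the 237 miRNAs called up or down (adjusted p under 0.05) against the shams of the same batch and time, for each dose and time (red bars up, blue bars down). Counts are 29 or fewer at 6 h, reach 169 at 48 h after 15 Gy, and at 7 d are 4 after 4 Gy and 150 after 8 Gy.

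Whether changes follow dose was tested as a linear trend over 0 to 8 Gy, which steps at 1 dose can also pass. At 48 h miR-1187 and miR-574-5p rose by 0.55 ± 0.06 and 0.54 ± 0.05 per Gy (SE, n = 3 per dose). For miR-574-5p most of the rise was there after 2 Gy. Its log2 levels were -8.04 to -7.33 on sham arrays, -4.96 to -3.40 after 2 Gy and -2.87 to -2.64 after 8 Gy. miR-150-5p fell by 0.26 ± 0.02 and miR-140-5p fell by 0.39 ± 0.04 per Gy, the latter with changes of -3.36, -3.64 and -3.75 after 2, 4 and 8 Gy, mostly a step to 2 Gy. At 7 d a linear slope sums up steps. miR-328-3p (0.92 ± 0.04 per Gy) changed by -0.44, -0.15 and 6.99 after 2, 4 and 8 Gy, miR-144-3p (0.30 ± 0.04 per Gy) by -0.07, -0.77 and 2.36, and miR-34a-5p (0.23 ± 0.02 per Gy) by 1.82, 1.71 and 2.17. The 8 Gy size of miR-34a-5p is open, as given above. At 24 h miR-30c-5p (0.16 ± 0.03 per Gy) changed by 0.98, 1.71 and 1.36, and at 6 h miR-342-3p and miR-146a-5p both rose by 0.12 per Gy. limma called 2 (2 up), 48 (34 up, 14 down), 155 (102 up, 53 down) and 154 (91 up, 63 down) trends at 6 h, 24 h, 48 h and 7 d. Normexp correction and the series matrix gave 0 at 6 h. Normexp correction gave 9 up and 77 down at 24 h, 55 and 47 at 48 h and 196 and 19 at 7 d. Quantile normalization gave 24 and 20 at 24 h and 80 and 68 at 48 h, and the series matrix gave 57 and 70 at 7 d. Without 24 h 8 Gy replicate 1 the count at 24 h was 26, and with the slide as a block 0 trends were called at 6 h and 11 at 24 h. The 2 trends at 6 h fell to 0 or 1 in 8 of the 12 fits that left out an array.

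Whether 15 Gy does more than 12 Gy was asked directly. At 48 h miR-1930-5p was 0.86 ± 0.17 higher after 15 Gy (SE, n = 3, adjusted p = 0.00023), miR-378a-5p 0.71 ± 0.17 and miR-375-3p 0.53 ± 0.06. miR-375-3p was below background in most other groups, so its pooled error is too small. limma called 12 miRNAs at 48 h (9 up, 3 down, or 3 and 3 with quantile normalization), 6 without 12 Gy replicate 3 and 19 without 15 Gy replicate 3. It called 0 at 6 h (31 at an unadjusted p under 0.05) and at 24 h (9). At 6 h the count was 64 with the slide as a block and 62 within shared slides, both resting on the 1 dim 15 Gy array, and 27 or 24 without 15 Gy replicate 2 or 3. With only the 6 compared arrays, with normexp correction or in the series matrix it called 0 at 48 h.

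Batch A and batch B shams were compared to learn how far the batches differ without irradiation. miR-150-5p was 0.80 ± 0.18 lower in batch B at 6 h and 1.17 ± 0.18 higher at 7 d (SE, n = 3). miR-342-3p was 1.19 ± 0.26 higher at 7 d, miR-17-5p was 0.94 ± 0.22 lower at 6 h and miR-101b-3p was 0.96 ± 0.24 lower at 48 h. miR-212-3p was at least 2.30-fold higher at 24 h. limma called 3 (0 up, 3 down), 20 (16 up, 4 down), 3 (0 up, 3 down) and 17 (6 up, 11 down) at 6 h, 24 h, 48 h and 7 d. Quantile normalization gave 1 and 3 at 6 h and 17 and 28 at 24 h. Normexp gave 4 and 3 at 24 h and 0 and 1 at 7 d, and the series matrix gave 10 and 0 at 24 h and 5 and 2 at 7 d. With only the 6 compared arrays the counts were 0, 0, 1 and 35 in order of time. Without 24 h sham B replicate 3 the 24 h count was 4. Leaving out 1 array gave 0 to 18 calls at 6 h, 1 to 4 at 48 h and 3 to 12 at 7 d. At 6 h 0 were called without sham A replicate 2 or sham B replicate 3, so the calls named there depend on single arrays.

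The 8 and 12 Gy changes share no array, so their likeness was measured across the 237 miRNAs, which are not independent replicates. Pearson's r was 0.60 at 6 h, 0.65 at 24 h, 0.97 at 48 h and 0.96 at 7 d, with jackknife SE over arrays of 0.24, 0.24, 0.0085 and 0.0088. Spearman's rho was 0.48, 0.69, 0.96 and 0.93. At 48 h 101 miRNAs rose in both against 52 by chance and 37 fell in both against 8. At 7 d 89 rose and 51 fell in both, against 39.2 and 14.7. Both irradiated groups at 7 d were the dimmest, with mean percentiles of 1585 and 1633, so an effect of scaling could be shared by both. Without scaling, 12 of 91 risers at 8 Gy and 33 of 102 at 12 Gy were still called up. At 24 h 1 miRNA of 66 called in both had opposite directions, and at 48 h and 7 d none of 138 and 140 did. In the series matrix r at 6 h was 0.358, and leaving out 1 array gave r from 0.390 (without 8 Gy replicate 3) to 0.688 at 6 h and from 0.465 (without 8 Gy replicate 1) to 0.808 at 24 h.

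**Figure D4:**
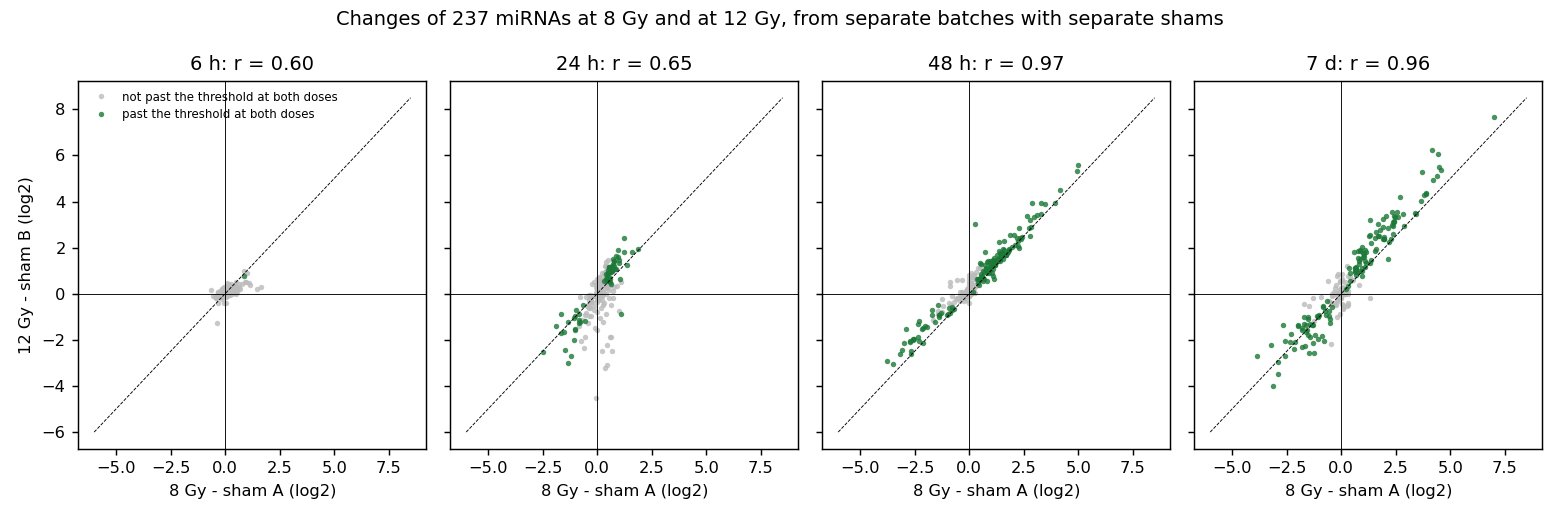
Change of each of the 237 miRNAs after 8 Gy (x axis) and 12 Gy (y axis), log2 against the shams of the same batch and time, in 1 panel per time (green, called at both doses; grey, not; dashed line, equal changes). Pearson's r is 0.60 at 6 h and 0.97 at 48 h.

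Whether the response differs among the 4 times was tested for 8 and 12 Gy, where limma called 181 and 192 of 237 miRNAs. miR-328-3p changed by -0.01, 0.40, 3.31 and 6.99 at 6 h, 24 h, 48 h and 7 d after 8 Gy, and miR-3107-5p by 0.13, 0.68, 1.53 and 3.90. miR-375-3p after 12 Gy was at least 8.20-fold higher at 48 h and below background in both groups at 6 h and 7 d. From one time to the next, 20, 126 and 132 changes differed after 8 Gy and 92, 109 and 109 after 12 Gy.

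Of 209 list tests, 5 were called, 4 up (myeloid 3 times, p53-linked once) and 1 down (miR-29 and miR-30 families), and 1 held with an estimated correlation. The smallest adjusted p of the uncalled lists was 0.215 for erythroid, 0.124 for lymphoid, 0.124 for pan-leukocyte, 0.236 for platelet, 0.124 for the miR-17-92 and paralogue clusters, 0.124 for let-7, 0.386 for inflammatory and 0.215 for other tissues miRNAs. The median, mean and test of a list differed in sign in 8 of 19 comparisons for erythroid, 9 for lymphoid, 1 for myeloid, 2 for pan-leukocyte, 10 for platelet, 5 for p53-linked, 5 for the miR-17-92 clusters, 2 for let-7, 2 for the miR-29 and miR-30 families, 12 for inflammatory and 8 for other tissues. In the inflammatory list miR-21a-5p fell by 0.98 ± 0.19 after 8 Gy at 24 h and by 1.42 ± 0.19 at 48 h (SE, n = 3), when miR-132-3p and miR-146b-5p rose.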

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

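Chosen only after the result was seen were the tests of the slide for the 7 d rises after 12 Gy, of fewer leukocytes and of the sham component at 48 h, and the overlaps given for 24 h.

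The size of the response differed among the 4 times for 181 miRNAs after 8 Gy and 192 after 12 Gy, by limma's test of the difference itself. After 8 Gy the smallest adjusted p values were those of miR-5119 (1.3e-25; at least 6.72-fold higher at 7 d, with both groups at the floor at 6 h, 24 h and 48 h), miR-328-3p (1.7e-21), miR-712-5p (1.1e-20), miR-3107-5p (8.6e-20), miR-150-3p (1.1e-19) and miR-671-5p (4.9e-19). After 12 Gy they were those of miR-375-3p (5.1e-42; at least 8.20-fold higher at 48 h), miR-671-5p (1.2e-28), miR-1895 (6.5e-27), miR-5119 (5.4e-26), miR-3072-5p (3.3e-25) and miR-150-3p (9.4e-25). Of these, miR-5119, miR-712-5p, miR-671-5p, miR-375-3p and miR-3072-5p were below background on every array of most groups, so their pooled error is too small and their p values overstate the evidence. At 48 h a signal outside the tested values also differed: the number of probes above background averaged 397.1 ± 45.8 (SD, n = 15, 333 to 485) on irradiated arrays and 313.3 ± 28.8 (SD, n = 6, 268 to 348) on sham arrays.

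The rises at 7 d after 8 and 12 Gy came with arrays 9.94-fold and 6.58-fold dimmer than their shams before scaling. Differences between slides are argued against. All arrays of the 12 Gy comparison lay on 1 slide, so its 161 calls are the main count itself and not a further test. Between 8 and 4 Gy arrays of 1 slide 144 were called, with 85 of the 91 risers and 52 of the 59 fallers of 8 Gy among them. Scaling to a lower percentile stays open, since without scaling the median change of the risers was -0.128 (jackknife SE 0.252) at 12 Gy and -1.04 (jackknife SE 0.411) at 8 Gy. Without scaling 33 of 102 and 12 of 91 risers were still called up, and miR-328-3p was 5.68 and 4.05 higher after 12 and 8 Gy. Of the risers, 50 and 26 were also higher without scaling and 52 and 65 lower. Loss of the abundant miRNAs that set the scale was not tested, and a biological response to dose stays open.

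The 29 calls at 6 h after 15 Gy may rest on 1 dim array: without 15 Gy replicate 1, whose raw percentile was 2145, 5 miRNAs were called. A graded response with dose is also open, since r across miRNAs with the 8 Gy changes at 6 h, which share no array, was 0.543, and 0.540 without that array. The count was 3, 5 and 4 without sham replicates 1, 2 and 3, and 48 without 15 Gy replicate 2.

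For the falls and rises at 48 h after 12 Gy, fewer leukocytes stays open. Of 14 members of the pan-leukocyte and lymphoid lists 6 rose and 5 fell, with a median change of 0.2115. Of all 237 miRNAs 122 rose and 37 fell, with a median of 0.388. The changes are relative to abundant blood miRNAs, so members that rose cannot decide. Array brightness is not decided either. The 8 Gy changes at 48 h, on brighter arrays, and at 7 d, on dimmer arrays, had r = 0.682 across miRNAs. A response shared by both times also gives a positive r, and the 12 Gy arrays did not enter. At 48 h the 12 Gy arrays averaged 12392 ± 4528 (SD, n = 3) before scaling, against 9977 ± 2262 (SD, n = 3) in their shams. An axis that also separates arrays of 1 group stays open too: the first component of deviations from group means, 26.6% of their variance, had an absolute r of 0.559 with the changes. With the first component of the sham deviations, 46.8% of theirs, the absolute r was 0.367, which decides neither way. At 24 h both overlaps were larger after 12 Gy, 0.822 with the first and 0.770 with the sham component (0.778 after 15 Gy), and another split of the 6 arrays called 90 miRNAs against the real 135. Such an axis stays open for the 24 h changes too. A response to dose stays among the open explanations.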

How the results depend on the processing

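The lower floor, the slide as a random block, the shared slides alone and the fit without the array of high negative-control spread were chosen only after the data were seen. A count was taken as kept within 1.5 times the main count, and a correlation within its jackknife SE of the main r. Of 37 summaries, 35 were kept with the lower floor and without the noisy array, 32 with the replicate block and 30 of 36 with the slide as a random block. With quantile normalization and with total gene signal 29 were kept, without a filter 26 and in the series matrix 24. Only the compared groups kept 22, normexp 17, the slide block 17 of 29 and the shared slides 10 of 14. Of 718 values of named miRNAs, 697 kept their call and were not reversed with the replicate block, 673 without a filter and 642 with total gene signal. The count was 637 with quantile normalization, 632 with normexp, 630 in the series matrix and 625 with only the compared groups. A value counted as reversed only where its sign changed and the main fit or the alternative called it. Sign changes of values called in neither fit count as kept. Signal over background limits the 8 and 12 Gy groups at 7 d, with mean raw percentiles of 1585 and 1633 and 189 and 207 probes above background, where miR-150-5p and miR-126-3p could not be bounded. Scaling over all probes gave no value, since that percentile was 0 or lower on 6 arrays. The slide as a fixed block could not be estimated for 2, 4 and 8 Gy and the trend at 7 d, for the shams at 48 h and 7 d, and for 8 Gy by time. Except where fewer or more miRNAs or arrays entered by construction, the cause was not tested.

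With normexp the counts were 0 at 8 and 12 Gy and 9 at 15 Gy at 6 h; 50, 54, 127 and 88 at 2, 4, 8 and 12 Gy at 24 h; 108 at 15 Gy at 48 h; 16 and 0 at 2 and 4 Gy at 7 d; 0, 86 and 102 for the trends at 6 h, 24 h and 48 h; 0, 7, 0 and 1 for the shams at 6 h, 24 h, 48 h and 7 d; and 0 for 15 against 12 Gy at 48 h. Its r at 7 d was 0.967 and it called 27 lists. Normexp moved the median of all miRNAs by more than 0.1 in 22 comparisons, from -0.67 (8 Gy at 24 h) to 2.22 (8 Gy at 7 d).

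With quantile normalization the counts were 3, 0 and 5 at 2, 4 and 8 Gy at 6 h, 2 at 4 Gy at 7 d, 45 and 1 for the shams at 24 h and 48 h, 6 for 15 against 12 Gy at 48 h, and 3 lists; it moved the median by -0.38 and -0.51 at 12 and 15 Gy at 48 h. In the series matrix they were 0 at 4, 8 and 12 Gy at 6 h, 1 at 4 Gy at 7 d, 0 for the trend at 6 h, 0, 10, 0 and 7 for the shams at 6 h, 24 h, 48 h and 7 d and 0 for 15 against 12 Gy at 48 h, with r of 0.358, 0.959 and 0.925 at 6 h, 48 h and 7 d. The matrix moved the median by -0.39 and -0.51 at 12 and 15 Gy at 48 h and by -0.24 and -0.45 at 8 and 12 Gy at 7 d.

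With total gene signal the counts were 2 at 2, 4 and 12 Gy and 7 at 15 Gy at 6 h, and 37, 1 and 7 for the shams at 24 h, 48 h and 7 d, with r of 0.934 at 7 d. Without a filter they were 0, 2, 0 and 264 at 4, 8, 12 and 15 Gy at 6 h, 0, 32, 1 and 5 for the shams in order of time, 246 for 15 against 12 Gy at 6 h and 60 lists, with r of 0.956 at 48 h. With only the compared groups they were 0 at 4, 8, 12 and 15 Gy at 6 h, 25 and 30 at 8 and 12 Gy at 24 h, 74 and 27 at 2 and 4 Gy at 7 d, 6 for the trend at 6 h, 0, 0, 1 and 35 for the shams in order of time, 0 for 15 against 12 Gy at 48 h, and 2 lists.

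With the slide block the counts were 9, 0, 0, 2 and 75 from 2 to 15 Gy at 6 h, 0 and 11 for the trends at 6 h and 24 h, 54 and 4 for the shams at 6 h and 24 h, 64 for 15 against 12 Gy at 6 h, and 3 lists, with r of 0.928 at 48 h. Within shared slides they were 10, 2 and 74 at 2, 12 and 15 Gy at 6 h and 62 for 15 against 12 Gy at 6 h. With the slide as a random block they were 2 at 12 Gy and 1 for the trend at 6 h, 1 and 9 for the shams at 48 h and 7 d, and 18 and 7 for 15 against 12 Gy at 6 h and 48 h. The replicate block gave 0 at 12 Gy at 6 h and 0, 0, 1 and 2 for the shams in order of time; the replicate numbers do not pair the arrays, as 26 of 81 arrays were closest to one of their own number. Without the array of high negative-control spread the counts were 5 at 15 Gy and 6 for the shams at 6 h. With the lower floor the counts were 1 for the trend at 6 h and 6 for 15 against 12 Gy at 48 h. With an estimated correlation 1 list was called.

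Leaving out each array in turn gave, at 6 h, 0 to 2 calls at 2, 4, 8 and 12 Gy and for the trend, 3 to 48 at 15 Gy, 0 to 18 for the shams (18 without sham A replicate 1) and 0 to 27 for 15 against 12 Gy (27 without 15 Gy replicate 2 and 24 without replicate 3). The trend at 24 h ranged from 26 (without 8 Gy replicate 1) to 63, the shams at 24 h from 4 (without sham B replicate 3) to 26, and 15 against 12 Gy at 24 h from 0 to 3. The shams at 48 h ranged from 1 to 4 and at 7 d from 3 (without sham B replicate 3; 5 without sham A replicate 3; 6 without sham B replicate 1; 11 without sham A replicate 1) to 12, 15 against 12 Gy at 48 h from 6 to 19, and 4 Gy at 7 d from 2 to 3. r ranged from 0.390 (without 8 Gy replicate 3) to 0.688 at 6 h, from 0.465 (without 8 Gy replicate 1) to 0.808 at 24 h, from 0.960 to 0.972 at 48 h and from 0.943 to 0.959 at 7 d.

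These named values reversed, with a call in the main fit or in the alternative, and the cause was not tested. With normexp: let-7e-5p -0.39 and -0.82 at 4 and 8 Gy at 24 h and -0.53 at 2 Gy at 48 h, miR-1187 -0.20 at 8 Gy at 24 h, miR-34a-5p -0.31 and -0.032 at 2 and 4 Gy at 48 h; at 7 d after 8 Gy miR-494-3p 0.20, let-7e-5p 2.17, miR-126-3p 1.47, miR-130a-3p 0.16 and miR-150-5p 1.81, and after 12 Gy miR-140-5p 0.45, miR-126-3p 1.53, miR-150-5p 1.05 and miR-342-3p 1.54; per Gy, let-7e-5p -0.091 and miR-34a-5p -0.082 at 24 h, and miR-494-3p 0.0073, let-7e-5p 0.27, miR-126-3p 0.16, miR-130a-3p 0.00053 and miR-150-5p 0.24 at 7 d; and miR-202-3p -0.25 between shams at 24 h. With quantile normalization at 48 h: let-7a-5p -0.19, let-7i-5p -0.072 and miR-130a-3p -0.71 after 12 Gy, and let-7a-5p -0.22, let-7g-5p -0.29, let-7i-5p -0.044, miR-130a-3p -0.70 and miR-342-3p -0.79 after 15 Gy. Also with quantile normalization, let-7i-5p was -0.072 at 4 Gy at 24 h, and miR-451a at 7 d was -0.60 and -0.74 after 8 and 12 Gy and -0.078 per Gy. For miR-451a these values do not decide its direction, as the highest-ranked probes cannot rise under that method. In the series matrix at 48 h: let-7e-5p -0.13 after 2 Gy; let-7a-5p -0.50, let-7e-5p -0.10, let-7i-5p -0.21 and miR-130a-3p -0.68 after 12 Gy; let-7a-5p -0.35, let-7e-5p -0.10, let-7g-5p -0.89, miR-130a-3p -0.66 and miR-342-3p -0.80 after 15 Gy. In the series matrix at 7 d after 8 Gy let-7d-5p was -0.51, let-7i-5p -0.44 and miR-21a-5p -0.53, and let-7i-5p was -0.052 per Gy. With total gene signal let-7e-5p was -0.12 at 15 Gy at 6 h, let-7g-5p -0.27 at 15 Gy at 48 h and miR-342-3p -0.078 at 8 Gy at 7 d. With the slide block miR-34a-5p was -0.98 between shams at 6 h.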

Other observations

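The comparisons of hairpin arms and of times with each other were chosen only after the data were seen.

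The arms of several hairpins moved apart. At 48 h after 8 Gy, miR-140-5p fell by 3.75 while miR-140-3p rose by 0.93, miR-150-5p fell by 2.29 while miR-150-3p rose by 1.59, miR-18a-5p fell by 2.57 while miR-18a-3p rose by 2.36, and miR-93-5p fell by 0.90 while miR-93-3p rose by 1.65. Of 15 hairpins with both arms called at 8 Gy, 9 had opposite directions, against a mean of 7.43 with arms shuffled, and at 12 Gy it was 7 of 12 against 5.51. Whether these counts exceed the shuffled ones was not tested.

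Across miRNAs, the 8 Gy changes at 24 h and 48 h had r = 0.751 and those at 48 h and 7 d r = 0.682, and for 12 Gy r was 0.783 and 0.772. The 6 h changes had r of at most 0.283 with any later time at 8 Gy and 0.275 at 12 Gy.

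A split of 3 arrays against 3 has 10 forms, too few for a share under 0.05, so only the counts are given, the real split first and the highest other after it. At 6 h they were 0 and 5 for 2 Gy, 1 and 0 for 4 Gy, 1 and 3 for 8 Gy, 1 and 0 for 12 Gy and 29 and 23 for 15 Gy, with 10, 1, 3, 1 and 1 of the 10 splits as large. At 24 h they were 94 and 0, 110 and 0, 70 and 14, 135 and 90, and 124 and 42 for 2 to 15 Gy; at 48 h 138 and 73, 150 and 6, 152 and 0, 159 and 11, and 169 and 7; at 7 d 46 and 0, 4 and 0, 150 and 75, and 161 and 3 for 2 to 12 Gy, and in each of these only the real split, 1 of 10, was as large. For sham B against sham A they were 3 and 7 at 6 h and at 48 h (2 of 10 as large), 20 and 15 at 24 h and 17 and 0 at 7 d (1 of 10). For 15 against 12 Gy they were 0 and 43 at 6 h, 0 and 38 at 24 h (10 of 10) and 12 and 11 at 48 h (1 of 10), and the highest of these at 6 h and 24 h point to a structure of the samples. The highest 2 Gy split at 6 h has 1 side wholly on 1 slide, and within shared slides the real split called 10; the highest 15 against 12 Gy split at 6 h has 1 side wholly on 1 slide too, and within shared slides 62 were called, which rests on 1 dim 15 Gy array. The highest split at 24 h also has 1 side wholly on 1 slide, but there 0 were called within shared slides, with 1 15 Gy array, so whether the slide is that structure stays open.

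Each count out of 100 given here includes the real split itself. Of 100 splits of the arrays among doses, 8 gave as many trends as the real 2 at 6 h (highest other 20). At 24 h 11 gave as many as the 48 (highest other 113), so chance cannot be excluded at 6 h or 24 h. Only the real split, 1 of 100, reached the 155 at 48 h (highest other 140) and the 154 at 7 d (highest other 136), where chance can be excluded. The draws for the trends exchanged sham and irradiated arrays too. They ask whether the dose groups differ at all, so they cannot tell a graded change from a step at 1 dose. For the response by time, 2 of 100 were as large as 181 after 8 Gy (highest other 182). After 12 Gy only the real split, 1 of 100, was as large as 192 (highest other 176). These draws exchanged irradiated and sham arrays within each time. They ask whether dose had any effect, so they cannot tell whether chance makes the response differ among times. For the correlation of 8 and 12 Gy changes, the 100 are all splits within each dose and its shams, none of them drawn. Chance cannot be excluded at 6 h, with 8 of 100 as large as 0.60 (highest other 0.821), or at 24 h, with 16 of 100 as large as 0.65 (highest other 0.832). It can at 48 h (0.97, highest other 0.956) and at 7 d (0.96, highest other 0.939), where only the real split, 1 of 100, was as large. For the lists, 52 of 100 gave at least the 5 calls (highest other 14), so chance cannot be excluded.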
